A study of Mus musculus with 2 samples.

How the data were processed

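Total RNA libraries from the hippocampus of 2 male B6CASTF1/J mice aged 36 days were used, each with its own biological replicate number and biosample in the labels, and each with 1 technical replicate. The labels give both samples the same donor identifier, which was read as that of the strain, so that they are 2 animals rests on the replicate numbers and biosamples. The tissue label is layer of hippocampus, and the part that was dissected is not given. Per the labels, RNA was purified with a column kit for animal tissue, 300 ng entered each library, and ERCC spike-ins of a profile for stranded, ribosomal RNA-reduced libraries were added. Each library had 3 tables. The authors' gene table gives an expected count and TPM per gene, and per the file headers its columns are those that RSEM writes. A first transcript table has the same columns with the share of each transcript in its gene as a percent, also deposited by the authors. A second transcript table holds an estimated count and TPM per transcript, and per the file headers its columns are those that kallisto writes; per the deposited description of the files it was derived from a single FASTQ file and an index, and the first tables from a transcriptome alignment and an index. The deposited gene table also gives, per the file headers, a posterior standard deviation of each count, which was used only to mark shared reads. The reference was mm10 with GENCODE M21 per the deposited description of the files. The programs, their versions, the aligner and the strand setting are not given in the sources used here, so genes that overlap on opposite strands are uncertain. The sums of the deposited TPM columns show that the authors scaled TPM over all entries of a table, spike-ins included. In the first tables the effective length was the length minus 99 bases, and in the second about 339 and 342 bases below the length in replicates 1 and 2, which bears on short transcripts most.

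All 55536 mouse gene identifiers matched the GENCODE M21 annotation, which gave symbols, classes and coordinates. Of these genes, 55450 had transcripts in the second table. Rows for ERCC transcripts, for the phage phiX and for numeric identifiers were kept out of gene counts and tests. They held 0.421% and 0.408% (ERCC), 0 and 1 counts (phiX) and 2.7e-05% and 1.3e-05% (numeric identifiers) of the total in replicates 1 and 2. Expected counts were rounded to whole numbers before tests. A gene was marked as sharing reads where its expected count was not whole by more than 0.005 and its posterior standard deviation was at least 1% of the count in the same library, for either library; 3457 genes were marked, which held 7.90% and 8.09% of gene counts. Read shares of such copies depend on the authors' model.

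Libraries were scaled by the trimmed mean of M values (TMM) of edgeR 4.0.16 in R 4.3.3. The common biological coefficient of variation came from edgeR's common dispersion on 18278 genes with a mean rounded count of at least 10. Genes were compared between the libraries by an exact two-sided binomial test on rounded counts, with Benjamini-Hochberg adjustment over 18270 genes with a mean expected count of at least 10; genes under an adjusted p of 0.05 and at least 1.5-fold apart were called apart. Folds are ratios of scaled counts with 0.5 added and are not corrected for transcript length. Intervals are exact 95% Clopper-Pearson intervals of the binomial share. A gene at 0 counts is taken as up to 3 counts, 0.104 and 0.101 CPM in replicates 1 and 2. This limit is one-sided, and a fold against it leaves out the counting error of the other library, so the exact two-sided interval reaches lower. Intervals and floors cover counting error only. Reads without molecular identifiers are not independent molecules. A group of 2 animals cannot separate an animal's biology from its dissection, and leaving 1 library out ends every test between them.

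Gene lists, 36 with 390 entries and 371 distinct genes, were fixed before the data were examined, as were the tests between the libraries and of these lists; the second lists and the tests of explanations came after the first results. Of the distinct genes, 344 passed 1 TPM in both libraries. For each list the median log2 ratio of members was set against 10000 random lists of the same size, drawn from 20 bins of mean expression; lists outside the central 95% were called shifted. The genes named are the 4 highest members of each list and those under 1 TPM in both libraries, all sex markers, the 10 most abundant genes outside the mitochondrial genome, the 10 highest by fold in each library among genes apart with at least 1 TPM and 50 counts on average, the 5 protein-coding genes farthest apart between tables in each direction with at least 5 TPM, and members of shifted lists that were apart; some of these genes are not reported here. The tables were compared on summed transcript TPM with 0.01 added.

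The procedures were tested on simulated data. For the comparison of the libraries, Poisson counts were drawn for 18270 genes from their real means with 200 genes changed. Of these, 88.0% of 100 genes changed 2-fold and 90.0% of 100 genes changed 4-fold were called. Among the unchanged genes 0.006% were called. The draws held no spread beyond Poisson noise and no shared reads, so these rates do not carry over to the real libraries. For the dispersion, a simulated coefficient of variation of 0.1 was returned as 0.0998, and Poisson counts gave 0.010. For the list percentiles, negative binomial counts were drawn; 0 of the 36 lists were called without a simulated change, and a dentate list raised by 0.4 on the log2 scale lay at percentile 100 with a median of 0.44. Alternatives were DESeq2 1.42.0 size factors, library totals, ERCC totals, other count, TPM and fold minimums, the second table, random lists matched on length too, TPM without mitochondrial genes, and each replicate left out where a value remained. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9 were used. No allele-specific values were analysed here.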

Results

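Total RNA was sequenced from hippocampal tissue of 2 male F1 hybrid mice of the strain B6CASTF1/J, offspring of a C57BL/6J and a CAST/EiJ parent, at 36 days of age. The tissue label is layer of hippocampus and the description says hippocampus, so which part was dissected is not given. Both samples carry the same donor identifier in the labels, with different biosamples, and they were read as 2 animals. The labels give the libraries as biological replicates 1 and 2 of a single group, each made from 300 ng of RNA with added ERCC spike-in transcripts. With 1 group there was no comparison between conditions. The comparisons are which genes and cell type markers the tissue expressed, how far the animals differed, and how far the deposited transcript tables differed. Replicate 1 held 28786216 expected counts and replicate 2 held 29755033. Of 55536 annotated mouse genes, 14879 reached 1 TPM, a measure of relative abundance corrected for transcript length, in both libraries, and 12733 of these were protein-coding, 57.8% of the annotated protein-coding genes. Coordinates are of mm10. Levels are given as mean TPM ± SD over the 2 libraries.

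The tissue expressed markers of each hippocampal neuron class that was examined. Camk2a, a kinase subunit of excitatory synapses, had 1380.3 ± 47.6 TPM (SD, n = 2). Nrgn, a calmodulin-binding protein of dendritic spines, had 616 ± 28.2 TPM, the vesicular glutamate transporter Slc17a7 had 546 ± 11.4 TPM, and the transcription factor Neurod6 had 70.8 ± 7.79 TPM. All 8 excitatory neuron genes passed 1 TPM in both libraries. Among markers of the CA1 field, Mpped1 had 72.2 ± 7.21, Wfs1 67.7 ± 8.10, Ccn3 47.4 ± 8.75 and Fibcd1 45.8 ± 5.80 TPM. For the CA2 field, Pcp4 had 110.2 ± 6.07 TPM, Rgs14 38.4 ± 1.12, Amigo2 8.62 ± 0.842 and Cacng5 5.03 ± 0.339 TPM, and Map3k15 stayed under 1 TPM in both libraries at 0.690 ± 0.0141. All 7 CA3 markers passed 1 TPM, led by Cpne4 at 47.7 ± 1.10 TPM, Elavl2 at 39.0 ± 1.34, Bok at 25.1 ± 0.622 and Nectin3 at 23.1 ± 1.61 TPM. Dentate granule markers were led by Rfx3 at 53.9 ± 5.30 TPM, Prox1, the transcription factor of granule cell identity, at 39.0 ± 8.61, Stxbp6 at 30.9 ± 0.375 and C1ql2 at 29.3 ± 3.94 TPM. Hilar mossy cell markers were lower, with Ajap1 at 18.1 ± 1.03, Calb2 at 17.7 ± 0.219, Calcrl at 3.43 ± 0.354 and Drd2 at 1.23 ± 0.0566 TPM, while Csf2rb2 was under 1 TPM in both libraries. Of the subiculum markers, Fn1 had 20.4 ± 0.728 TPM, Slc17a6 5.99 ± 0.00707, Nts 5.46 ± 1.44 and Tpbg 3.54 ± 1.32 TPM, and Teddm3 was under 1 TPM in both. Genes of dentate neurogenesis were detected at low levels. Neurod1 had 12.7 ± 1.02 TPM, Sox4 9.73 ± 0.219, Sox11 9.03 ± 1.49 and Dcx, a microtubule protein of immature neurons, 7.05 ± 0.594 TPM, whereas Mki67, Draxin and Eomes stayed under 1 TPM in both libraries.

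Inhibitory neurons and glia were represented in both libraries. All 16 interneuron genes passed 1 TPM, and the neuropeptide genes Cck and Sst had 274 ± 8.35 and 161 ± 17.9 TPM, the GABA-synthesising enzyme Gad1 138 ± 1.95 TPM and the cannabinoid receptor Cnr1 72.5 ± 6.87 TPM. The astrocyte glutamate transporters Slc1a2 and Slc1a3 had 741 ± 2.503 and 163 ± 1.57 TPM, Aldoc had 348 ± 8.80 and Gfap 122 ± 6.70 TPM. Myelin genes included Mbp at 726 ± 4.49 TPM, Mobp at 222 ± 13.1 and Cnp at 104 ± 9.67 TPM. Oligodendrocyte precursor genes were lower, with Gpr17 at 19.02 ± 2.28, Pdgfra at 17.3 ± 2.09, Cspg4 at 8.43 ± 0.905 and Vcan at 8.40 ± 0.679 TPM. The microglial genes Csf1r, Ctss and C1qb had 28.6 ± 0.891, 22.4 ± 1.07 and 19.6 ± 0.898 TPM. Endothelial Ly6c1, Cldn5, Itm2a and Flt1 lay at 28.1 ± 2.71, 19.3 ± 3.78, 16.6 ± 0.106 and 16.0 ± 0.127 TPM. Among mural cell genes, Vtn had 25.98 ± 2.48, Rgs5 20.7 ± 2.38, Acta2 6.70 ± 0.120 and Pdgfrb 5.96 ± 1.52 TPM, and Kcnj8 was under 1 TPM in both libraries.

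**Figure D1:**
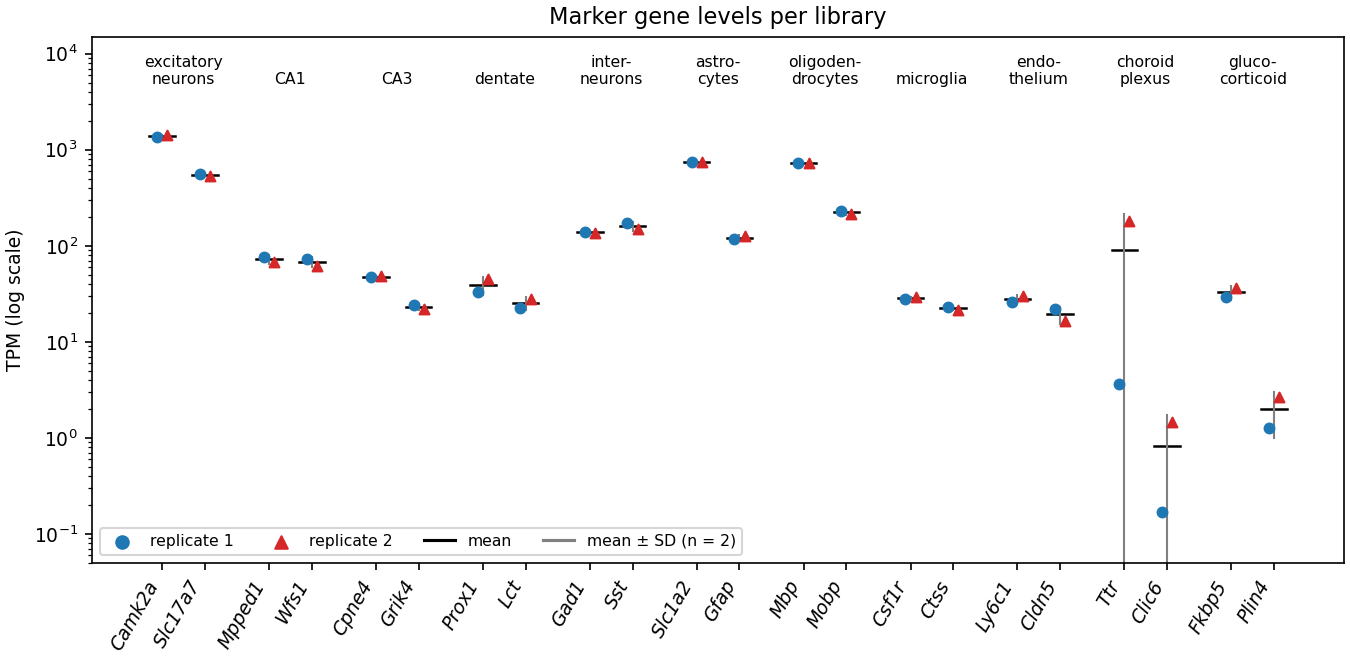
TPM on a log axis of 22 marker genes in replicate 1 (circles) and replicate 2 (triangles), with the mean (black line) and mean ± SD (grey line, n = 2, drawn to the lower edge of the axis where it reached below 0). Ttr stood at 3.62 TPM in replicate 1 and 179 TPM in replicate 2, while Camk2a had 1347 and 1414 TPM.

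Markers of neighbouring regions and of non-neural tissue were detected as well. For the thalamus, Prkcd had 12.8 ± 0.608, Plekhg1 7.18 ± 1.12, Tcf7l2 4.61 ± 0.318 and Lef1 2.76 ± 0.156 TPM. For the striatum, Pde10a had 27.2 ± 0.0848, Ppp1r1b 19.3 ± 0.0141, Rgs9 6.32 ± 0.530 and Drd1 2.37 ± 0.163 TPM, and for the neocortex Fezf2 had 18.7 ± 3.48, Tshz2 14.8 ± 1.80, Cux2 13.0 ± 0.127 and Rorb 8.13 ± 1.05 TPM. Ependymal genes were near the detection limit, with Rsph1 at 5.62 ± 0.0283 and Foxj1 at 2.10 ± 0.297 TPM, Ccdc153 at 0.990 ± 0.0424 TPM, and Mlf1, Tmem212 and Dynlrb2 under 1 TPM in both libraries. Meningeal genes included Ptgds, the prostaglandin D synthase, at 248 ± 97.1 TPM, Igf2 at 36.6 ± 7.495, Dcn at 19.04 ± 6.85 and Col1a2 at 6.60 ± 1.40 TPM, and Slc22a6 was under 1 TPM in both. The haemoglobin genes Hbb-bs, Hba-a1, Hba-a2 and Hbb-bt had 113 ± 21.8, 109 ± 17.8, 85.5 ± 13.6 and 13.9 ± 0.134 TPM, and each shared reads with another copy, so their division is uncertain. The Y-linked genes Eif2s3y, Ddx3y, Uty and Kdm5d had 30.9 ± 2.09, 18.6 ± 0.339, 11.5 ± 1.22 and 8.63 ± 0.177 TPM, and Xist, the RNA that coats the inactive X chromosome of females, had 0.0350 ± 0.0212 TPM from 9 and 6 counts.

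Genes of synaptic transmission were expressed in both libraries. All 22 genes of the synaptic machinery passed 1 TPM, with Snap25 at 793 ± 38.0, Syp at 699.6 ± 27.5, Camk2b at 443 ± 19.1 and Vamp2 at 393 ± 18.1 TPM. Of the 15 ionotropic glutamate receptor genes, Gria2 and Gria1 had 291 ± 8.26 and 288 ± 3.63 TPM and Grin1 and Grin2a had 173 ± 9.21 and 163 ± 0.255 TPM. Grm5 led the metabotropic receptors at 105 ± 5.30 TPM, ahead of Grm7 at 30.9 ± 0.113, Grm2 at 28.8 ± 4.47 and Grm3 at 27.5 ± 0.304 TPM. The GABA-A receptor subunit gene Gabra5 had 71.1 ± 1.73 TPM, and the sodium channel subunit genes Scn2a and Scn2b had 102 ± 6.43 and 102 ± 3.13 TPM. Of the activity-regulated immediate early genes, Homer1 had 78.4 ± 1.30 TPM, Arc 42.7 ± 5.97, Egr3 33.6 ± 0.679 and Egr1 25.02 ± 0.615 TPM, and Egr2 was under 1 TPM in both libraries. The clock output gene Tef had 115 ± 8.51 TPM, Cry2 40.1 ± 0.311, Hlf 36.2 ± 2.86 and Per1 35.1 ± 2.26 TPM. Imprinted genes are those whose parental copies can differ in expression. They were led by the noncoding RNA Meg3 at 1135 ± 125 TPM, Gnas at 701 ± 18.4, Rian at 488 ± 41.5 and Snrpn at 334 ± 15.1 TPM. Magel2, H19 and Rtl1 were under 1 TPM in both libraries. Levels here are summed over both alleles.

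Short noncoding RNAs held the largest TPM values. Rn7s1 and Rn7s2 on chromosome 12 (69159295 to 69159594 and 69361182 to 69361481), copies of the RNA of the signal recognition particle, each had 156549 TPM in replicate 1 and 161503 TPM in replicate 2, with identical values for the copies and reads shared between them. Rn7sk, an RNA that holds back transcription elongation, had 54971 ± 747 TPM (chromosome 9, 78175303 to 78175633). Gm26917, annotated as a lincRNA (chromosome 17, 39843013 to 39846341), followed at 12289 ± 469.5 TPM, and the source of its reads was not tested. Then came Rpph1, the RNA of ribonuclease P, at 7304 ± 299 TPM and the nuclear RNA Malat1 at 6121 ± 0.544 TPM. The 10 most abundant genes annotated outside the mitochondrial genome also held 3 unprocessed pseudogenes on chromosome 1. These were Gm28661, Gm10925 and Gm28437, at 7016 ± 189, 6283 ± 122 and 4254 ± 455 TPM. A copy of Rmrp had 2654 ± 311 TPM, and all 4 had shared reads. Which entries the 3 pseudogenes shared reads with was not examined, so their levels are uncertain. The 2 annotated copies of Rmrp summed to 4805 and 5005 TPM in replicates 1 and 2. Protein-coding genes took 41.3 ± 0.533% of TPM but 78.4 ± 0.0374% of expected counts. The class misc_RNA took 37.3 ± 0.776% of TPM and 5.52 ± 0.171% of counts. It holds Rn7s1 and Rn7s2, which made up most of its TPM, and Rn7sk. Genes annotated on the mitochondrial genome took 10.1 ± 0.198% of TPM. The replication-dependent histone genes Hist1h4h, Hist1h4d, Hist1h4i and Hist1h1c, whose messages lack a poly(A) tail in dividing cells, had 133 ± 23.1, 51.7 ± 2.47, 25.4 ± 4.72 and 21.5 ± 0.820 TPM.

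The 2 animals were close over most genes and apart in a small set. Among set members without shared reads and with at least 1 TPM and 50 counts on average, Ttr, the transthyretin gene, had the largest fold. Across genes, Pearson's r of log2(TPM + 1) was 0.995 and Spearman's rho 0.941; genes are not independent replicates, so no p-value is given. Among 18270 genes with a mean expected count of at least 10, 92.8% lay within 1.5-fold, and the common biological coefficient of variation was 0.0644. The exact two-sided binomial test, with Benjamini-Hochberg adjustment and a minimum of 1.5-fold, placed 328 genes beyond counting noise, 213 of them higher in replicate 2 and 115 higher in replicate 1. Of the 328 genes, 128 shared reads with another gene copy, a larger share than the 1924 of all 18270 genes tested. When such genes were left out 200 remained, 132 higher in replicate 2 and 68 higher in replicate 1. This test compares the 2 libraries, each from 1 animal, and has no replicate check. Its folds are ratios of scaled counts, and for some genes TPM gives a smaller or opposite difference. Zic1 and Xdh were apart and higher in replicate 2 by counts. They had 4.06 and 3.64 TPM, and 4.65 and 3.98 TPM, in replicates 1 and 2. In the second table the TPM of both was higher in replicate 2.

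**Figure D2:**
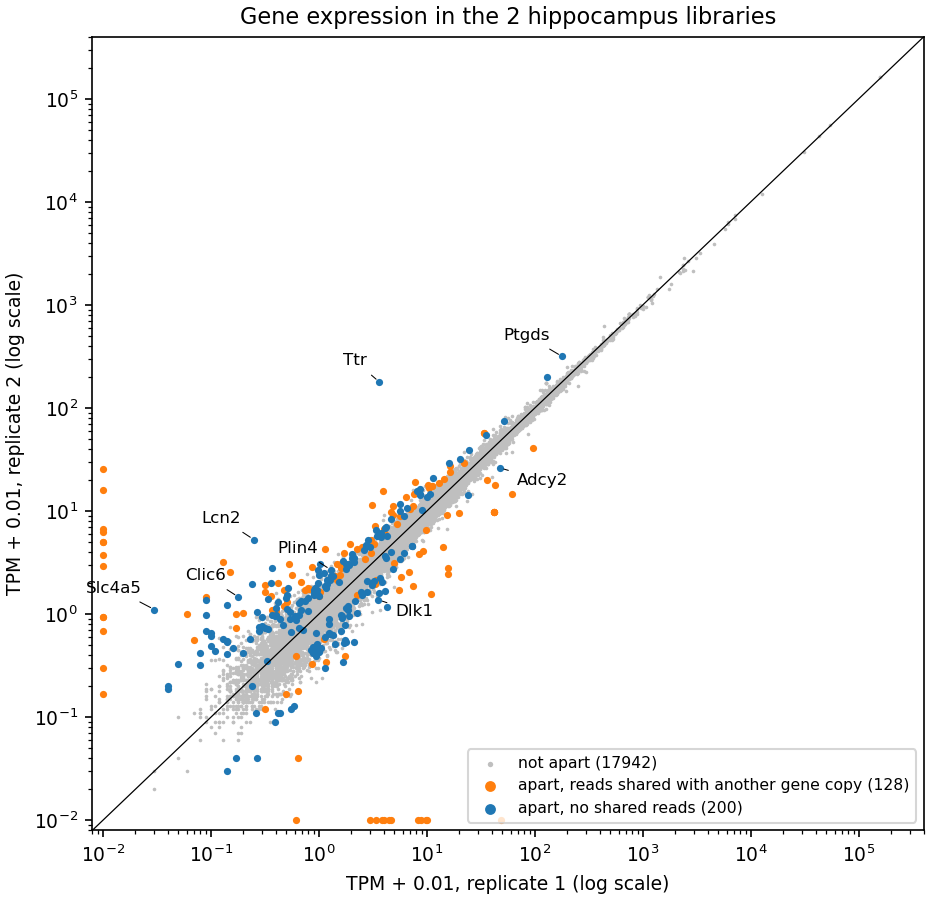
TPM plus 0.01 in replicate 1 (horizontal, log axis) and replicate 2 (vertical, log axis) for the 18270 genes tested, with the line of equality. Grey points are the genes not apart, orange points the 128 apart genes that shared reads with another copy, and blue points the 200 apart genes that did not; Ttr stood at 3.62 and 179 TPM.

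Choroid plexus genes were higher in replicate 2, all 11 tested members in the same direction and 9 of them beyond counting noise (9 when adjusted over the list alone). Ttr (ENSMUSG00000061808.4, chromosome 18, 20665280 to 20674321), which the choroid plexus secretes into the cerebrospinal fluid, had 81 counts in replicate 1 and 4202 in replicate 2, a 50.1-fold difference (95% exact Clopper-Pearson interval, 40.5 to 63.7). The chloride channel gene Clic6 differed 8.32-fold (4.84 to 16.6), the water channel Aqp1 11.6-fold (4.75 to 49.0), the bicarbonate transporter Slc4a5 18.5-fold (5.98 to 194), the folate receptor Folr1 7.02-fold (2.76 to 30.3) and the coagulation factor gene F5 6.404-fold (3.75 to 12.5). Otx2 at 3.22-fold (1.56 to 8.00), Sostdc1 at 2.07-fold (1.37 to 3.24) and Enpp2 at 1.52-fold (1.45 to 1.60) were also apart, while Kl and Prlr, at 1.30-fold and 1.45-fold, did not reach the fold minimum. Otx2, Aqp1, F5 and Kcne2 stayed under 1 TPM in both libraries, and Kcne2, with 1 and 18 counts, was too low to be tested. The list median of the log2 ratio was 2.68, at percentile 100 of 10000 random lists matched on expression, and 0.57 at percentile 100 among members with a mean count of at least 100. The median TPM of the list rested on replicate 2, at 1.70 TPM against 0.33 TPM in replicate 1.

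Glucocorticoid response genes were also higher in replicate 2, with all 10 members in that direction and 3 of them apart (3 when adjusted over the list alone). Plin4, a lipid droplet protein gene (chromosome 17, 56100591 to 56109803), differed 2.14-fold (1.76 to 2.62; adjusted p = 2.16e-13 by the exact binomial test). The cell cycle inhibitor gene Cdkn1a (chromosome 17, 29090976 to 29100727) differed 2.05-fold (1.64 to 2.58; adjusted p = 2.90e-09, exact binomial test) and Hif3a 1.69-fold (1.45 to 1.96). By TPM Hif3a differed less, at 4.28 and 5.71 in replicates 1 and 2. The more abundant members lay below the fold minimum: Zbtb16 at 53.8 ± 7.30 TPM was 1.25-fold, Sgk1 at 51.0 ± 10.3 TPM 1.42-fold, and Tsc22d3 at 48.0 ± 9.46 TPM 1.39-fold higher in replicate 2, and Per1 was 1.17-fold higher. The list median was 0.48 on the log2 scale, at percentile 100. The library with these higher values is the one with the higher choroid plexus transcripts.

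Dentate granule markers were higher and CA1 markers lower in replicate 2. All 10 dentate markers had higher counts there, with a median log2 ratio of 0.33 at percentile 100; Prox1 differed 1.41-fold (1.36 to 1.47), and the desmosomal gene Dsp, at 1.60-fold (1.47 to 1.76), was the 1 member apart (1 when adjusted over the list alone). The CA1 list had a median of -0.24 at percentile 0.0, with 7 of 8 members higher in replicate 1 and none apart, and the subiculum list a median of -0.26 at percentile 0.87 with none apart (-0.385 without genes that share reads). Dentate neurogenesis genes had a median of 0.22 at percentile 99.7, none of them apart. The medians of the CA2 list (0.08), the CA3 list (0.09), the mossy cell list (0.01) and the general excitatory list (-0.04) lay within the central 95% of random lists.

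In all, 21 of the 36 gene lists fell outside the central 95% of random lists, 10 towards replicate 2 and 11 towards replicate 1, and most of these shifts were small. Members of a list can vary together within an animal, which random lists do not reproduce, so the percentiles describe these libraries only. The ratios are of scaled counts, and no list shift was tested on TPM. The median TPM of the clock, dentate neurogenesis and imprinted lists went against the shift, and that of the other shifted lists went with it. A list's median TPM does not compare the libraries member by member. Towards replicate 2 lay heat shock genes (median 0.24, 8 of 8 members, and 0.11 without genes that share reads), with Hspa1a at 1.52-fold and Hspb1 at 1.53-fold apart, both with shared reads and Hspa1a no longer apart in the second table, and with Hspa8, Hsp90aa1, Hsph1 and Dnajb5 at 971 ± 35.0, 418 ± 6.41, 155 ± 12.3 and 81.2 ± 8.72 TPM not apart. Meningeal genes lay there too (median 0.33), although Ptgds was 1.78-fold (1.69 to 1.87) higher in replicate 2 and Dcn, a matrix proteoglycan gene, 1.69-fold (1.51 to 1.89) higher in replicate 1. Clock genes had a median of 0.12, with Per2 apart at 1.53-fold (1.41 to 1.65), and thalamic markers a median of 0.23 and immediate early genes 0.08 with no member apart. The shift of the immediate early genes was lost in the second table (0.06) and at a mean count of at least 100 (0.07). Histone genes had a median of 0.29 with no member apart (1 when adjusted over the list alone), and the shift was lost without genes that share reads, where the median was 0.00 over the few members left. Towards replicate 1 lay the blood list (median -0.30), where 4 of 5 members share reads and the 1 left without them lay at -0.20, too few to tell whether the shift rests on shared reads, endothelial genes (-0.21), mural cell genes (-0.15, and -0.065 and not shifted in the second table) and oligodendrocyte genes (-0.14). The myelin-forming cell marker Opalin was the only oligodendrocyte gene apart, 1.60-fold (1.33 to 1.93) higher in replicate 1, with a log2 ratio of -0.515 and no longer apart in the second table. Interneuron (-0.11), imprinted (-0.08), GABA-A receptor (-0.06), channel (-0.05) and synaptic (-0.04) lists were shifted by less. Scaled to ERCC totals these medians were -0.075, -0.042, -0.025, -0.013 and -0.006. Such scaling moves all genes alike and cannot change a percentile. At a mean count of at least 100 the synaptic median stayed at -0.04, and its percentile passed from 1.49 to 2.63, just inside the central 95%. Among imprinted genes Dlk1 was apart, 2.33-fold (1.81 to 3.04) higher in replicate 1, with 200 and 88 counts. Within the central 95% of random lists lay the medians of astrocytes (0.02), oligodendrocyte precursors (0.02), microglia (-0.07), ependymal cells (0.07), striatum (0.05), neocortex (-0.11), ionotropic and metabotropic glutamate receptors (-0.04 and 0.01), noncoding RNAs (0.00), sex markers (-0.06) and isoform genes (-0.03). Over all lists 20 distinct members in 8 lists were apart, and the histone list was the only 1 of the 36 whose count changed when adjusted over the list alone.

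**Figure D3:**
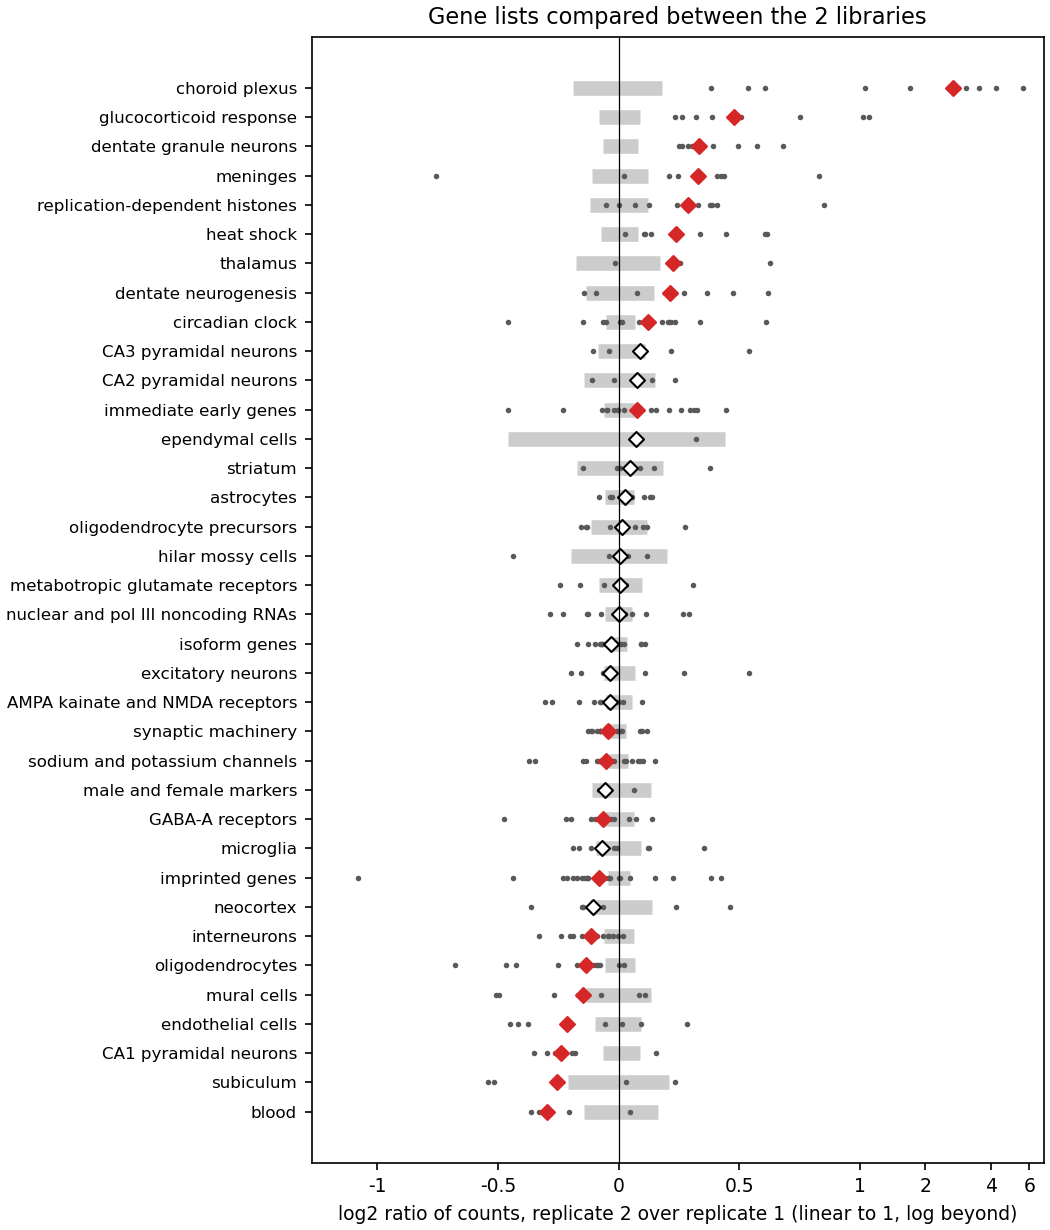
Log2 ratio of scaled counts, replicate 2 over replicate 1, for members with a mean count of at least 10 (grey points) of 36 gene lists; the axis is linear up to 1 and logarithmic beyond. Diamonds are list medians, red where outside the central 95% of 10000 matched random lists (grey bars); choroid plexus genes reach a median of 2.68, and all other shifted medians are at most 0.48 from 0.

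Among the genes that were highest by fold, many shared reads with another annotated gene. Of the 10 genes highest in replicate 2, Ttr, the kinase gene Map3k6 at 2.62-fold (1.90 to 3.70) and the sulphate transporter gene Slc13a4 at 2.44-fold (1.84 to 3.31) had no shared reads. Map3k6 differed less in TPM, at 1.29 and 2.35 in replicates 1 and 2, and 3.97 and 4.72 in the second table. Gm14288, Gm13394, Gm6361 and Gm12070 had 0 counts in replicate 1 after rounding and were at least 116-fold, 101-fold, 60.7-fold and 42.0-fold higher in replicate 2, taken against 3 counts (lower ends of the exact intervals, 93.6, 81.2, 48.8 and 33.8), and together with Gm4767, H3f3c and Gm3435 they shared reads and are uncertain. In the second table the log2 ratio of Gm14288 was 0.24 and that of Gm3435 0.80, neither apart, and Gm4767 changed direction to -0.30. All 10 genes highest in replicate 1 shared reads: Nnt on chromosome 13, Gm11847, Gm5559, Gm10359, Myl12b, the 4 U3 small nucleolar RNA genes Rnu3b1, Rnu3b2, Rnu3b3 and Rnu3b4, and AC123659.1. Nnt, a mitochondrial transhydrogenase gene, is annotated under 2 identifiers that overlap on the same strand, at 119335448 to 119408997 and 119335528 to 119408952. The latter identifier had 295 counts in replicate 1 and 0 in replicate 2. It was at least 101-fold higher in replicate 1 when taken against 3 counts (lower end of the exact interval, 81.7). Over both identifiers the counts summed to 588 and 609, so the difference lies in how reads were divided between them. In the second table that Nnt identifier changed direction to a log2 ratio of 0.40, and Gm11847 and Myl12b, at -0.75 and -0.325, were not apart. Outside that rule, and chosen after their values were seen, the genes without shared reads that stood highest by fold in replicate 1, among those with at least 1 TPM and 50 counts on average, were Dio3, the thyroid hormone inactivating enzyme, at 2.54-fold (1.89 to 3.49), and Dlk1. Both lie on chromosome 12, Dlk1 at 109452823 to 109463336 and Dio3 at 110279068 to 110281097. Adcy2, an adenylyl cyclase gene on chromosome 13 (68620043 to 68999541), had 4014 and 2327 counts, 1.77-fold (1.69 to 1.87) higher in replicate 1.

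The 2 deposited transcript tables gave different levels for short RNAs. In the second table Rn7sk had 0.87 TPM in replicate 1, and genes shorter than 350 bases with a mean count of at least 50 held 0.0086% of estimated counts against 5.97% in the first. Of these 103 genes, 101 had less than 10% of their first-table count. Genes of 700 bases or longer had a median log2 count ratio of 0.11 between the tables. Of 17246 genes with a mean of at least 1 TPM, 4094 differed at least 2-fold in both libraries, 3645 of them higher in the second table. The median over genes of the TPM ratio, second table over first, was 1.66 and 1.70 in replicates 1 and 2. The misc_RNA class took 37.3% of TPM in the first table and 0.0044% in the second. As TPM is scaled over all entries, this raises the other genes in the second table. After the tables were centred on each other 1663 genes differed, 1150 higher and 513 lower in the second table. The protein-coding genes with the largest fold towards the first table were mt-Atp8, Snurf, Rpl10-ps3, Rps12-ps3 and Hist2h2aa2, the 5 of them between 204 and 768 bases long, and all but mt-Atp8 shared reads. Those towards the second table were Gm47283 on the Y chromosome, at 250.2 and 207 TPM against a first-table value of 0.00 TPM, Gm21897, Olfr986, Gm49369 and Gm27027.

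For 20 brain genes with several isoforms, the most abundant transcript of the first table was the same in both libraries for all 20. The most abundant transcript held at least 50% of the gene's TPM in both libraries for 13 genes in the first transcript table and for 9 genes in the second, and 17 of the 20 genes had the same leading transcript in both tables. App-201 held 90.7 ± 1.28% of the amyloid precursor gene's TPM, Snap25-201 87.8 ± 0.962%, Mapt-204 69.2 ± 0.771% and Camk2a-203 64.6 ± 0.806%. In the first table the median difference between libraries was 1.67 percentage points and the largest, for Grin1, was 5.45. For the same transcripts in the second table the median was 1.53 and the largest, for Bdnf-205, was 11.5. The tables differed by a median of 4.78 points. The largest gap was for the myelin basic protein transcript Mbp-211, with 69.7 ± 3.09% in the first table and 33.9 ± 0.22% in the second, and Dlg4-203 had 57.2 ± 2.67% and 28.3 ± 0.78%. The leading transcript changed between tables for Grin1, Cnp and Pkm; for the glycolytic enzyme Pkm, Pkm-202 held 51.6 ± 1.94% in the first table, and Pkm-201 led the second with 46.6%.

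**Figure D4:**
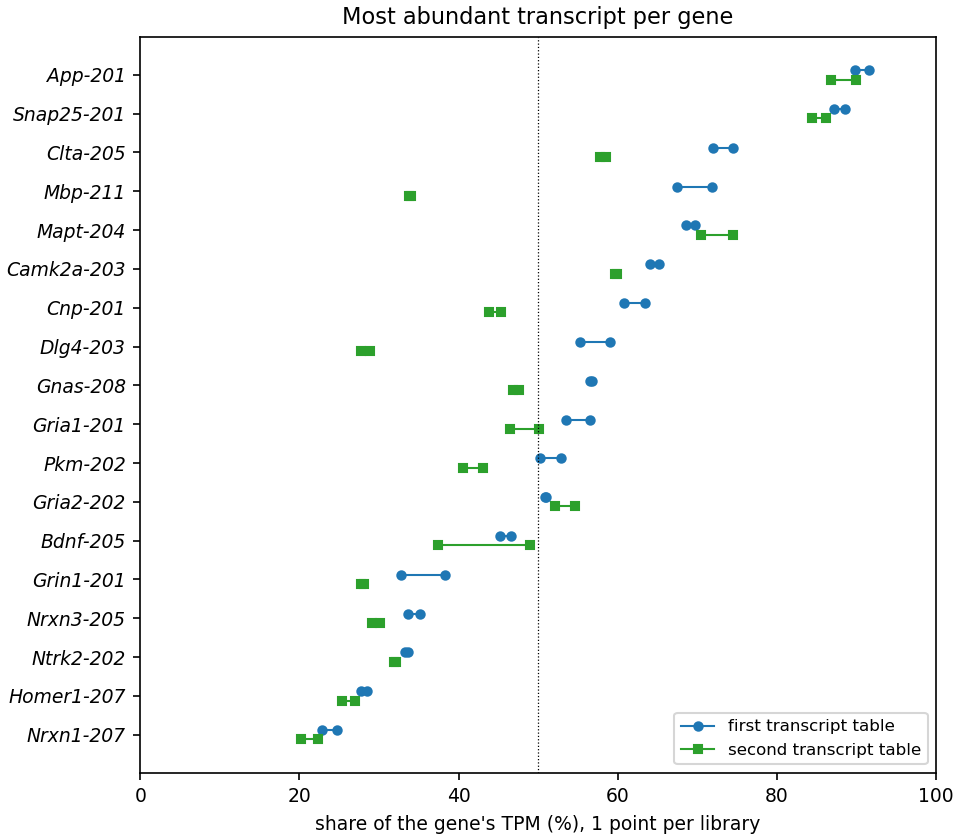
Share of the gene's TPM in its most abundant transcript, in percent, for genes of the list of 20, some of which are not drawn, with 1 point per library joined by a line (circles, first transcript table; squares, second transcript table), and a dotted line at 50%. Over all 20 genes the median difference was 1.67 percentage points between libraries in the first table and 4.78 between tables, and the widest gap between tables was for Mbp-211.

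Spike-in transcripts took 0.421% of expected counts in replicate 1 and 0.408% in replicate 2, a mean of 0.414 ± 0.0092% (SD, n = 2). Of the 96 ERCC transcripts, 60 had at least 1 count in both libraries, and across these the log2 TPM of the libraries had a Pearson's r of 0.989 and a Spearman's rho of 0.982, with transcripts not counted as replicates.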

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

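With 1 group of 2 libraries there was no outlier test and no second group to set against the first. Rows with numeric identifiers, which the labels and file headers do not explain and which entered no comparison, held 7.91 expected counts in replicate 1 and 4.0 in replicate 2. Both are above the 3 counts that a count of 0 allows, and no control sample was there to compare with. No explanation for them was tested.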

How the results depend on the processing

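The lists of alternatives were fixed before the data were examined, except for leaving out genes that share reads and centring the tables on each other, which were chosen after seeing the data. The number of genes apart, 328, depended most on the minimums and on genes that share reads. It was 113 with a mean count of at least 100 (fewer genes were tested), 2042 with no fold minimum and 172 at 2-fold. Without genes that share reads it was 200, also with fewer genes tested. It was 328, 324 and 367 with DESeq2 size factors, library totals and ERCC totals, 320 with no count filter and 303 in the second table, of which 158 were among the 328. Genes apart between quantifiers numbered 13629 at 1.5-fold, 1455 at 4-fold, 8287 and 1744 with a mean of at least 0.1 and 10 TPM, and 1663 with the tables centred, against 4094; without replicate 1 or 2 they numbered 5347 and 4940. The spike-in share was 0.746% of TPM and 0.296% of counts in the second table, against 0.414%, and the protein-coding share was 78.4% of counts against 41.3% of TPM; TPM divides by transcript length, and the cause of the difference in the second table was not tested. Genes detected ranged from 10517 (5 TPM) to 20991 (0.1 TPM), with 17353 in the second table and 15416 to 15477 with 1 library. Pearson's r stayed between 0.986 and 0.995 and the coefficient of variation between 0.0611 and 0.0646. The number of list members detected stayed between 344 and 351, and 9 to 14 genes had a dominant isoform, 14 and 13 without replicate 1 and 2. Of 36 lists, 19 to 21 were shifted in every alternative run. Size factors, library totals and ERCC totals move all genes alike and cannot change a list call, and in the other alternatives 137 of 144 calls were kept. There no median of the 21 shifted lists changed sign, and 5 of the 15 lists that were not shifted had a median that did. The choroid plexus median was 0.57 at a mean count of at least 100, and the heat shock median 0.11 without genes that share reads. With ERCC totals the GABA-A receptor, channel and synaptic medians were -0.025, -0.013 and -0.006. In the second table mural cells (-0.065) and immediate early genes (0.06) were no longer shifted. At a mean count of at least 100, immediate early genes (0.07) were not shifted either, the synaptic list kept its median of -0.04 and passed just inside the central 95%, and the neocortex list was shifted (-0.15). Without genes that share reads the histone median fell to 0.00, while the blood list was left with 1 of 5 members at -0.20, too few to decide. By the second transcript tables, Gm4767 and 1 of the 2 overlapping Nnt identifiers changed direction, to -0.30 and 0.40 on the log2 scale. Both share reads, and the cause was not tested. Gm14288, Gm3435, Gm11847, Myl12b, Opalin and Hspa1a kept their direction and missed the threshold there, at 0.24, 0.80, -0.75, -0.325, -0.515 and 0.57. List medians of TPM were a median of 1.62-fold higher in the second table. Depth limits genes with few counts, such as Kcne2 with 1 and 18, and 1 library per animal means that no call between the libraries has a replicate check.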

Other observations

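Of 20 genes of the endoplasmic reticulum stress response, 19 had higher scaled counts in replicate 2 and 6 were apart. These genes were chosen after their values were seen, so no test of the group is given. The chaperone gene Hspa5 had 130.0 and 201 TPM in replicates 1 and 2, a 1.61-fold difference (1.56 to 1.66), and Creld2, Sdf2l1, Pdia4, Herpud1 and the transcription factor gene Xbp1 differed by 1.93, 1.88, 1.64, 1.57 and 1.56-fold. Canx and Dnajb9, at 1.02 and 0.972-fold, were not apart. Of 11 tested ATF4 pathway genes, also chosen after the fact, 10 were higher in replicate 2 and none was apart, and Atf4 and Asns, an amino acid synthesis gene, were at 1.03 and 1.01-fold. Lcn2, an acute-phase gene that is also on the second glucocorticoid list, had 4 counts in replicate 1 and 94 in replicate 2, 20.4-fold (8.63 to 85.6).

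Of the tests that follow, that on Ttr alone and that which set the glucocorticoid list against the dentate list were chosen after the result was seen. Each second list was read in the same 2 libraries as the first, so it is not independent support for a cause. The design names no biological difference between the animals, so none was tested against these explanations. The list of choroid plexus genes was higher in replicate 2. A rise of Ttr alone was argued against by the first result itself, in which Clic6, Aqp1 and other members were also apart. The list without Ttr kept percentile 100 with a median of 2.18, which restates that result and adds no separate evidence. Choroid plexus tissue in the replicate 2 dissection is a candidate explanation: a second list of 11 choroid plexus genes, written before it was tested, had a median of 1.47 at percentile 100 over the 8 members with enough counts, with Kcnj13, Cldn2, Tmem72 and Calml4 apart, and the abundant Ttr reached 179 TPM. Of the 12 and 11 genes on these lists, 4 and 2 were at 1 TPM or more in replicate 1, and 4 and 8 were under 1 TPM in both libraries. How such tissue would have entered stays open.

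Glucocorticoid response genes were higher in replicate 2. A trend with GC content or length as the whole cause was argued against, because the list stayed at percentile 100 among random lists matched on expression, GC content and length, and across genes the log2 ratio had a rho of -0.018 with GC content and 0.031 with length. A wider glucocorticoid target response is a candidate explanation. A second list of 15 such genes, written before it was tested, had a median of 0.40 at percentile 100. All 15 were higher in replicate 2, with Lcn2, Angptl4, Sult1a1 and Arrdc2 apart. By TPM Arrdc2 differed less, at 8.98 and 10.14 in replicates 1 and 2, and Lcn2 is also an acute-phase gene. The second list cannot separate a hormone response from other differences between the same 2 libraries. More dentate gyrus in replicate 2 cannot be told apart from such a response either. The glucocorticoid median exceeded the dentate median by 0.146, with a bootstrap 95% interval from -0.088 to 0.450 over few members. Hormone levels were not measured.

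Dentate granule genes were higher in replicate 2. A trend with GC content or length was argued against by percentile 100 in random lists matched on both. More dentate gyrus in the replicate 2 tissue is a candidate explanation, as a second dentate list of 8 genes had a median of 0.36 at percentile 100, with all 8 higher, and CA1 genes had a median of -0.24. The hilar mossy cell list, also of the dentate gyrus, did not go with it, with a median of 0.01 at percentile 51.5, but its 5 genes went both ways, 3 higher in replicate 2 and 2 in replicate 1, so it does not decide. A change of expression within granule cells was not tested and stays open.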
